A study of Mus musculus with 10 samples.

How the data were processed

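The 10 samples were mouse embryonic stem cell libraries of 2 kinds. The 6 ChIP-seq libraries came from chromatin immunoprecipitation with guinea pig antibodies against RAD23B or with normal guinea pig IgG: 2 RAD23B and 2 IgG libraries from wild-type D3 cells and 1 of each from Xpc-null cells. The 4 RNA-seq libraries came from the JM8.N4 line, 1 each from wild-type cells, Rad23b-null cells and Rad23b-null cells with Xpc knocked down by either of 2 independent hairpins (knockdown 1 and knockdown 2). The groups were taken from the labels. The RAD23B library of wild-type replicate 2 was assigned by its antibody label, because its title also holds the word IgG. Nothing in the labels says whether the replicates came from separate cultures. The IgG libraries have no list of their own.

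Each RAD23B library had 1 list of regions called against IgG, per the file headers, in mm9 coordinates. Partek is named for this in the submitters' processing notes, and the aligner, calling settings and thresholds are not given in the sources used here. Each list holds, per the file headers, counts of reads of the RAD23B and the IgG library in the region and the highest count of extended reads over any position. The deposited RPM is that maximum scaled to the reads of the library in which regions were called, so maximum over RPM gave 109.3 M reads for wild-type replicate 1, 62.53 M for replicate 2 and 145.1 M for the Xpc-null list. The scaled fold is the authors' ratio of the libraries in a region, and the p-values in these lists are the authors' too, with none above 0.05. These folds and p-values were used only to describe, rank or filter regions within a list. The headings in the replicate 2 list name the replicate 1 libraries, and the values differ from those of replicate 1. In the Xpc-null list the headings of the fold and the p-value name the wild-type replicate 1 IgG library. Its read columns are headed with the Xpc-null RAD23B and IgG libraries. In the Xpc-null list the authors' fold followed the reads in the column headed IgG over those in the column headed RAD23B (relative spread of the quotient 0.0014 over regions, against 0.275 for the direction the heading gives), and the maximum exceeded the column headed RAD23B in most regions. Either these 2 headings are exchanged or the regions were called in the IgG library; the values do not settle which, and read columns of that list are named below by their headings. Coordinates are given as in the deposited lists.

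Expression tables were made with TopHat2 2.0.6, Cufflinks 2.0.2 and Cuffdiff on mm9, per the submitters' processing notes, from poly-A RNA. Each table sets 1 mutant library beside the wild-type library, and its RPKM values were scaled by the authors separately for each table: wild-type values in the Rad23b-null table were 1.026 times those in the knockdown 1 table and 1.017 times those in the knockdown 2 table. Wild-type values printed below are those of the Rad23b-null table; ratios used the wild-type values of the same table. The deposited RPKM columns hold no 0, and exactly 1 stands in 13889 of the wild-type values while other values go far below 1, so exactly 1 was read as 0. The deposited ratio is mutant over wild-type RPKM, and the deposited p-value has 3 decimals with no adjustment stated; with 1 library per group it rests on no replicates. The tables hold no status, q-value or significance column, so the filter on status and the alternative at a q-value of 0.01 laid down for them could not be used. Of 36658 lines in each table, 72 name no gene (0.00144% of wild-type RPKM) and were left out, which left 36586 genes. Of these, 13068 share their listed coordinates with other genes, up to 156 on 1 locus, and 23518 have coordinates of their own. The sources do not say whether a value on shared coordinates is that of the gene or of the merged locus, which holds for Stk31, Bmp4, Psmc5 and Rpl19 too. The steps between low RPKM values gave the mutant libraries 1.29, 1.23 and 1.26 times the wild-type depth (Rad23b-null, knockdown 1, knockdown 2); the read totals of these libraries are unknown.

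Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Change was measured as the log2 ratio of RPKM + 1, mutant over wild type, among genes with an RPKM of at least 1 in either library, and genes were counted when at least 2-fold apart; this scale understates the change of low genes. With 1 library per group there was no test, and no p-value was computed. Random differences between genes were gauged from the 2 knockdowns, which differed from each other by a standard deviation of 0.65 on the log2 scale (middle 68% within 0.22 of 0), with 3.21% of genes at least 2-fold apart.

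The design, the comparisons, 21 gene lists, the rule for naming genes and most of the other settings tried were fixed before the data were examined. The lists were the XPC complex, nucleotide excision repair, core and naive pluripotency, Nodal and primed state, primitive endoderm, trophectoderm, mesoderm and primitive streak, neural ectoderm, 2-cell-like, germline, p53 targets, proteasome, unfolded protein response, heat shock, interferon response, glycolysis, cholesterol synthesis, replication-dependent histones, ribosomal proteins, fibroblasts (the feeder cells of stem cell cultures) and imprinted genes. A list's median log2 ratio was set beside 10000 random lists of the same size matched on mean expression in 10 bins, and its percentile describes these libraries only. A list was called apart when its percentile lay under 2.5 or above 97.5, which chance gives for 1.05 of 21 lists. Named genes were Rad23b, Xpc and Cetn2, the 10 highest and 10 lowest per comparison among genes with an RPKM of at least 5, the 8 highest and 8 lowest shared by both knockdowns, 2 to 4 members of each list by size of change, and Pou5f1, Sox2, Nanog, Klf4 and Esrrb. Names beginning with Mir, Snor or Gm or ending in Rik were left out of that ranking; the exclusion was extended to all short RNA types after the tables were seen. A few genes that this rule names are not reported here.

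Regions were compared by overlap of at least 1 bp, set beside 200 random placements within the same chromosomes. Shares carry exact (Clopper-Pearson) 95% confidence intervals, which cover counting error only. A gene had a region when a wild-type replicate 1 region that overlapped a replicate 2 region lay in its locus or within 5 kb, among genes with coordinates of their own. List shares were set beside 10000 random lists matched on wild-type RPKM, where genes of RPKM 0 are tied and fell into bins in listed order. The 2 knockdowns share the wild-type library, so unchanged libraries against a shared control were simulated 100 times. The noise in these simulations was drawn from the difference between the 2 knockdowns. Both were made in the Rad23b-null line, so the simulations hold no difference between the wild-type and Rad23b-null lines.

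The counting, list and overlap steps were tested on simulated data, with gene noise drawn from the knockdowns in the same way. Among 15040 simulated genes for the Rad23b-null comparison, the 2-fold rule found 4.0% of genes changed 1.5-fold, 46.0% of those changed 2-fold, 94.0% of those changed 3-fold and 96.0% of those changed 4-fold, and called 2.95% of unchanged genes. A simulated list lowered by 0.4 stood at percentile 0 and 5.0% of unshifted lists lay outside the range. Alternatives covered the pseudocount, the RPKM filter, centring, the distance and strictness of regions, the matching, each left-out wild-type RAD23B replicate and, added after seeing the data, chromosome, gene type, shared coordinates, tied RPKM of 0 and the reading of exact 1.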

Results

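XPC, RAD23B and CETN2 form the complex that recognises damaged DNA at the start of nucleotide excision repair. The 10 libraries asked where RAD23B sat on chromatin in mouse embryonic stem cells, what was listed in cells without Xpc, and which genes differed after loss of Rad23b alone or with knockdown of Xpc. RAD23B was profiled in 2 wild-type replicates and 1 Xpc-null library, each beside an IgG library, and expression in 4 single libraries.

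In wild-type cells RAD23B regions lay at the genes of the core pluripotency factors. At Pou5f1, which encodes OCT4, 4 regions were listed in both replicates; the strongest (chr17:35640617-35642553), upstream of the start, held 1645 RAD23B and 313 IgG reads in replicate 1 and an authors' fold of 5.00 and 6.29 in the replicates. A weaker region at the Pou5f1 start itself (chr17:35642594-35643304) had folds of 2.04 and 2.25. Nanog, a homeobox factor of naive cells, had a region upstream (chr6:122652186-122653530; 877 and 201 reads, folds 4.14 and 4.38) and another over its start (chr6:122656984-122657848; 3.39 and 3.87). Esrrb, a nuclear receptor gene, held 17 shared regions, of which chr12:87842359-87843414 reached folds of 5.597 and 6.947 (991 and 168 reads). The 578 kb listed locus that includes Sox2 held 14, up to 4.91 and 7.57, while Klf4 had 2 weaker ones (at most 1.87 and 1.98).

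**Figure D1:**
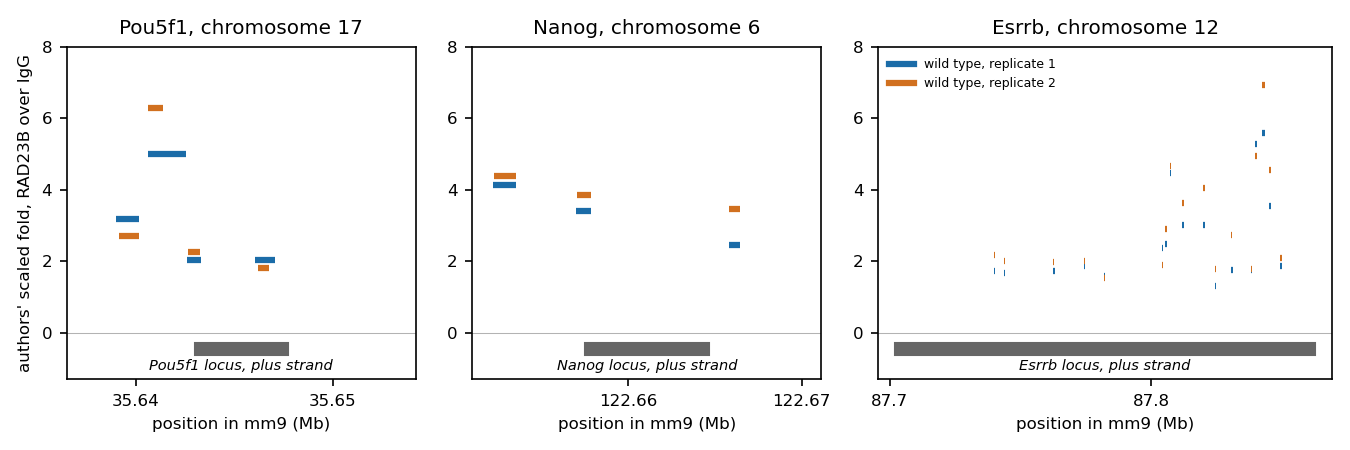
RAD23B regions at the Pou5f1, Nanog and Esrrb loci in wild-type replicate 1 (blue) and replicate 2 (orange), with the authors' fold as height. The strongest region lay upstream of Pou5f1 (folds 5.00 and 6.29), upstream of Nanog (4.14 and 4.38) and inside Esrrb (5.597 and 6.947).

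In all, 59768 regions were listed in replicate 1 and 42364 in replicate 2, covering 35.6 and 22.9 Mb, with median widths of 503 and 476 bp and median folds of 1.88 and 2.09. Of the replicate 1 regions, 38822 (64.95%) overlapped a replicate 2 region, against a mean of 2.16% after random placement (highest 2.32%), and 95.91% of replicate 2 regions overlapped replicate 1 (random mean 2.94%). The shared fraction climbed from 52.2% in the weakest decile of replicate 1 to 81.6% in the strongest, and folds of shared regions were correlated (Spearman 0.834). The highest fold of any listed region was 15.2 in replicate 1 and 25.5 in replicate 2. Among replicate 1 regions that overlapped a replicate 2 region, the 10 of highest fold lay mostly outside genes: chr3:3666704-3667208, the first of these (10.35 and 12.2 in replicate 2), lay 1909283 bp from the start of Pxmp3, and others stood near Pcdh17, Stk17b, Olfr901, Ccdc160, Pja1, Arxes2 and Gpc4. Of these 10 regions 4 were on the X chromosome and 1, chr11:62168694-62169214, lay inside a listed locus, that of Ncor1, Pigl and Ttc19. The lists differed in depth (109.3 and 62.53 M reads) and in lowest maximum (61 and 40 reads), so absence from replicate 2 can mean a region under its limit.

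In Xpc-null cells no region was listed at Pou5f1, Nanog, Klf4, Esrrb or the Sox2 locus. The whole list held 828 regions, of median width 223 bp and median authors' fold 1.56, which in this list is the column headed IgG over the column headed RAD23B. By that fold 84 regions were at 2-fold or more, and by the headings 0, against 24930 and 23856 in the wild-type replicates. Of the 38822 shared wild-type regions, 478 (1.23%, 95% confidence interval 1.12 to 1.35%) overlapped an Xpc-null region, and of the strongest decile by fold only 17 of 3883 (0.438%, 0.255 to 0.70%). In the other direction, 534 of the 828 regions (64.5%, 61.1 to 67.8%) overlapped replicate 1 and 491 (59.3%) replicate 2, against a random mean of 2.99%, and 280 (33.8%) overlapped neither. The replicate 1 regions they overlapped stood at a median percentile of 38.5 by fold but 93.1 by IgG reads. By maximum reads of the RAD23B library they stood at 89.8, so they were high in both libraries. The IgG rank takes all reads of a region, so wide regions rank high. Chromosome 8 carried 477 of the 828 (57.6%), against 7.58% of replicate 1 regions. Every Xpc-null region had more reads in the column headed IgG (median 82) than in the column headed RAD23B (median 42), so the list may describe IgG enrichment. The library in which these regions were called, RAD23B or IgG, held 145.1 M reads, has no replicate and had a lowest maximum of 65 reads (0.448 RPM, against 0.558 and 0.640).

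Genes active in the wild-type JM8.N4 library had RAD23B regions, mapped in wild-type D3 cells, far more often than inactive ones. A shared region lay in or within 5 kb of 6499 of 8445 genes with an RPKM of at least 1 (77.0%) and of 3530 of 15073 below 1 (23.4%), and within 1 kb of the start in 66.7% and 11.6%. Among protein-coding genes the shares were 85.4% and 29.6%. All told 10029 of 23518 genes (42.6%) had a region; 64.3% of shared regions lay in a locus, 11.1% within 5 kb and 24.6% farther away, with 19.9% within 1 kb of a start. Genes with a region had longer loci (median 14.7 kb against 1.02 kb), which raises the chance of holding one.

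**Figure D2:**
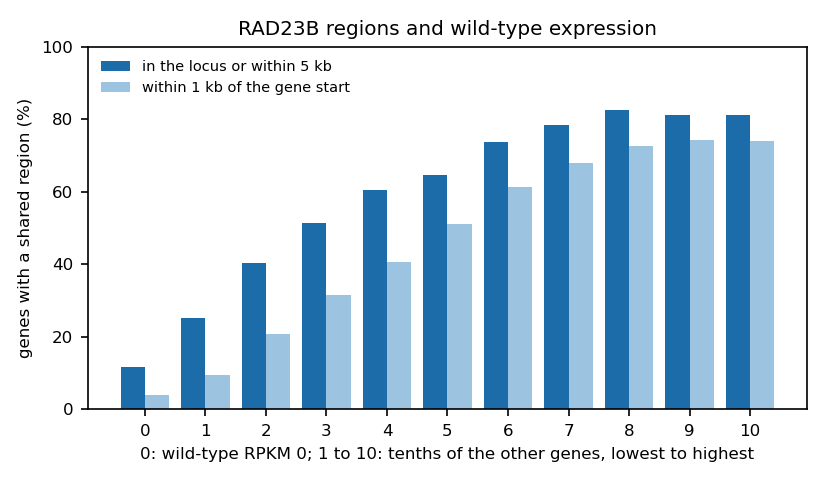
Share of genes with a shared RAD23B region for genes with a wild-type RPKM of 0 (group 0) and deciles of the other genes, for the locus with 5 kb around it and for 1 kb around the start. By locus the share was 11.7% in group 0, 25.1% in the lowest decile and 81.2% in the highest. Regions are from D3 cells and RPKM from JM8.N4 cells.

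p53 target genes all had a region (21 of 21, percentile 99.75 among lists matched on expression), as did the replication-dependent histone genes, which sit in clusters (25 of 25, percentile 100). The 2-cell-like genes, a family switched on in early embryos and in rare stem cells, had a region at 1 of 15 (percentile 0.32). These were the only 3 of 21 lists outside the middle 95% of lists matched on expression. Matched on expression and locus length, a setting chosen after the result was seen, 3 more lay outside. These were ribosomal protein genes (99.94), unfolded protein response genes (98.98) and germline genes (1.795). The 2-cell-like list includes Zscan4 genes, which are near copies of each other, and how well ChIP reads can be placed there was not examined. A missing region at these genes need not mean absent RAD23B. Pluripotency genes had a region at 23 of 25 (91.1), trophectoderm genes at 13 of 16 (95.6), glycolysis genes at 14 of 14 (97.48), unfolded protein response genes at 13 of 13 (96.7), heat shock genes at 8 of 8 (92.7), ribosomal protein genes at 20 of 21 (92.2), mesoderm genes at 12 of 17 (90.1) and interferon response genes at 11 of 18 (88.3). Excision repair genes stood at 12 of 14 (69.7), the XPC complex at 2 of 3 (10.8), proteasome genes at 18 of 20 (82.3), cholesterol synthesis genes at 13 of 15 (69.2), Nodal and primed genes at 10 of 13 (80.1), primitive endoderm genes at 10 of 16 (53.7) and neural genes at 7 of 11 (83.8). Germline genes (8 of 15; 6.39), fibroblast genes (7 of 17; 11.2) and imprinted genes (8 of 11; 34.3) were lower in the ranking. Members of a family or cluster can share regions, and the percentile treats them as separate.

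The transcripts aimed at were reduced but present. Rad23b, at 229 RPKM in wild type, stood at 43.9 in Rad23b-null cells, 35.8 in knockdown 1 and 52.5 in knockdown 2 (19, 16 and 23% of wild type); the tables do not say which part of the gene the remaining reads cover. Xpc, 8.73 in wild type, was 8.34 in Rad23b-null cells (95.5%) and 0.915 and 0.895 in the knockdowns (10.8 and 10.4%). Cetn2, the centrin of the complex, went from 44.2 to 30.4, 37.9 and 36.8. The authors' deposited table listed p-values of 0.001, 0 and 0.004 for Rad23b.

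Loss of Rad23b went with lower RNA of naive pluripotency genes while Pou5f1 and Sox2 moved less. Klf4, a Krüppel-like factor, went from 78.7 to 20.1 RPKM (log2 -1.92), Tfcp2l1, a factor that holds the naive state, from 177 to 44.7 (-1.96), Prdm14, which represses primed-state genes, from 19.8 to 5.07 (-1.77), and Tbx3, a T-box factor, from 40.1 to 11.9 (-1.67). Esrrb went from 162 to 51.5 (-1.63), Nanog from 512 to 198 (-1.37) and Dppa3, a protein of oocytes and naive cells, from 83.8 to 31.3 (-1.39). Pou5f1 went from 1603 to 1152 (-0.48) and Sox2 from 184 to 123 (-0.58); Zfp42, a marker of undifferentiated cells, held at 44.6 and 47.0. As a list, pluripotency genes stood at -0.41 relative to all genes (percentile 0.04), with 26 of 34 below the median of all genes and 9 at least 2-fold lower. Tfcp2l1, Tbx3 and Sox2 share listed coordinates with other genes, so their values may be those of a merged locus. The authors' deposited table gave p-values of 0 for Klf4 and 0.031 for Nanog, but 0.966 for Tfcp2l1 and 1.0 for Esrrb.

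**Figure D3:**
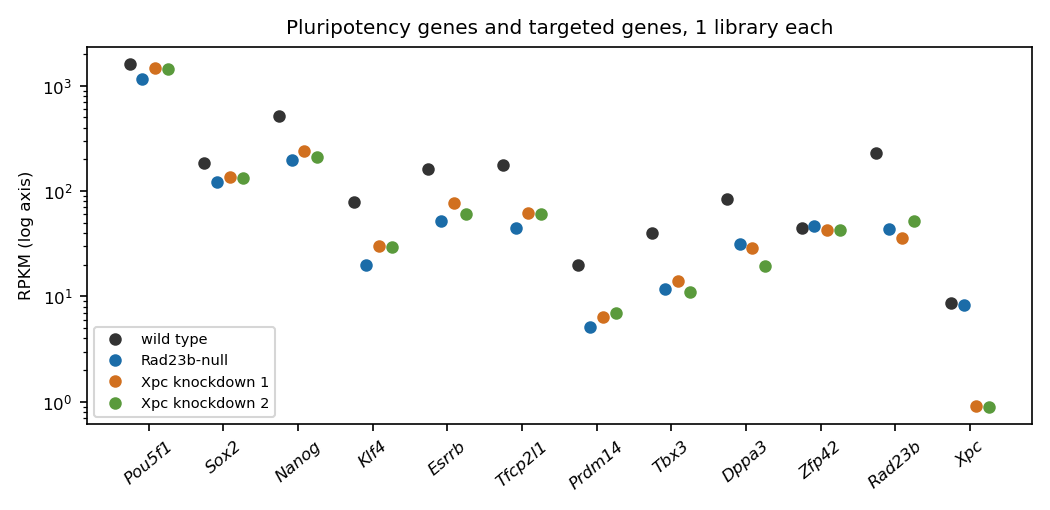
RPKM of pluripotency genes, Rad23b and Xpc in the 4 libraries, 1 library per group, on a log axis. Klf4 went from 78.7 to 20.1, 30.1 and 29.2, and Zfp42, chosen for this figure after its values were seen, from 44.6 to 47.0, 42.4 and 42.3.

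Genes of the 2-cell embryo were the list furthest up in Rad23b-null cells, from almost no RNA. Zscan4f, a zinc finger gene of that stage, went from 0.274 to 5.22 RPKM (log2 2.29), Zscan4c from 0.183 to 2.75 and Tcstv3 from 0 to 4.06, and the list stood at 1.47 relative to all genes (percentile 100; 8 of 11 at least 2-fold higher). Members near 0 in wild type count only when the mutant library lifts them over the RPKM limit, and over all 16 matched 2-cell-like members without that limit the list stood at 1.06 in Rad23b-null cells, 0.47 in knockdown 1 and 0.61 in knockdown 2 (percentile 100 in each). Germline genes followed at 0.87 (percentile 100), with Taf7l, a testis paralogue of a TFIID subunit, at 24.1 from 2.28, Stk31 at 15.98 from 3.65 and Mael, a piRNA pathway gene, at 27.0 from 8.76. Trophectoderm genes stood at 0.60 (99.94), led by Krt19 (15.2 to 78.7) and Hand1 (0.329 to 3.31), while Tfap2c was lower (59.2 to 22.4). p53 targets stood at 0.53 (percentile 100), with Perp, a death effector, at 75.4 from 29.7, Ddit4l at 20.5 from 6.96 and Cdkn1a, which encodes p21, at 39.7 from 26.5. The glycolysis list stood at 0.26 (99.99), or at 0.09 with only genes of their own coordinates. This list also holds genes that do not encode glycolytic enzymes, among them Bnip3 (352 from 269) and Vegfa (52.8 from 34.3). The enzyme gene Aldoc went from 79.9 to 38.8. Zscan4 genes are near copies of each other, so their reads are hard to separate.

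Below the matched range stood also proteasome genes (-0.41, percentile 1.46), with Psmb6 at 213 from 410 and Psmb3 at 145 from 361, cholesterol synthesis genes (-0.35, 0.865), with Fdps, on shared coordinates, at 39.4 from 119 and Insig1 at 38.6 from 74.9, and histone genes (-0.15, 0.535), whose transcripts mostly lack poly-A tails. Of the 32 proteasome genes 6 are on chromosome 11, Psmb6, Psmb3 and Psmc5 among them, and without that chromosome the list stood at percentile 3.04. With only genes of their own coordinates cholesterol synthesis stood at percentile 3.79 and the proteasome at 11.2, inside the range. Inside the range lay the XPC complex (-0.32, 21.4), excision repair (-0.16, 31.1), Nodal and primed state (0.11, 89.2), primitive endoderm (0.04, 41.8), mesoderm (0.52, 86.4), neural ectoderm (-0.05, 15.7), unfolded protein response (0.02, 92.6), heat shock (-0.29, 12.4), interferon response (0.07, 47.4), ribosomal proteins (-0.19, 86.7), fibroblasts (0.17, 74.8) and imprinted genes (0.04, 74.8). In those lists single genes still differed: Hspa8, a constitutive chaperone, went from 6691 to 2894, Rpa1, a single-strand binding protein, from 159 to 94.6, Lefty1, a Nodal antagonist, from 101 to 45.2, Bmp4 from 4.36 to 16.1, Neurog1 from 4.24 to 0.382, Cited1 from 1.77 to 5.92, Oas1a from 2.27 to 0.289 and S100a6 from 16.2 to 56.6. Of the 21 lists 9 lay outside the range, against 1.05 by chance, but the percentile treats genes as independent, and genes of a pathway vary together between cultures.

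Trh, the thyrotropin-releasing hormone gene, went from 242 to 27.6 RPKM in Rad23b-null cells, Tdh, the threonine dehydrogenase on which mouse stem cells rely, from 438 to 60.7, and Mpi, a mannose isomerase, from 16.9 to 2.55. Also among the 10 lowest were Mmp17 (69.5 to 4.73), Klhdc7a (7.45 to 0.216), the imprinted Nnat (9.54 to 0.532), Usp26 (11.4 to 1.21), Tspo2 (7.35 to 0.562), the metallothionein Mt4 (6.11 to 0.492) and Rad23b; Tdh and Nnat share coordinates with other genes. The 10 highest held Taf7l, Prmt2 (5.28 to 168), Stub1 (52.6 to 731), Chpf2 (2.03 to 31.3), Vps8 (10.3 to 92.9), Trps1 (2.17 to 24.3), Cbx8 (0.858 to 12.7), the pseudogenes Rpl35a-ps3 (0 to 69.2) and Hmgn2-ps1 (2.07 to 35.2) and an unplaced gene model; 5 of these 10 share coordinates with other genes. For Prmt2 and Stub1 the authors' deposited table gave p-values of 0.743 and 0.861. Among 15040 genes, 713 were at least 2-fold higher and 694 lower, 362 and 418 of them protein-coding. Simulated unchanged libraries, over 15459 genes of all types, gave on average 731 genes at least 2-fold apart in 1 comparison (highest 787), higher and lower together. This simulated count applies to the knockdown comparisons too. Its noise came from the 2 knockdowns, so it leaves out differences between the wild-type and Rad23b-null lines. Counts above it can hold such differences. The median log2 ratio of all genes was -0.16, and centring on it gave 933 higher and 462 lower, so the split between higher and lower depends on scaling. The authors' deposited table had a p-value under 0.05 for 416 genes, 225 higher and 191 lower. The difference between these groups has no replicate check.

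Knockdown 1 in Rad23b-null cells, set against wild type, again showed lower naive genes and higher 2-cell-like genes. Klf4 stood at 30.1 RPKM (log2 -1.32), Tfcp2l1 at 62.05 (-1.46), Esrrb at 77.0 (-1.02) and Nanog at 243 (-1.04), while Pou5f1 was 1468 (-0.09) and Sox2 135 (-0.40). The pluripotency list stood at -0.25 (percentile 1.37, or 4.52 with only genes of their own coordinates; 22 of 34 below the median of all genes), the XPC complex, which includes the targets, at -1.25 (0.03) and the proteasome at -0.31 (0.47, Psmb6 127, Psmc5 93.1). Higher were 2-cell-like genes (1.14, 100), with Zscan4f at 1.98 and Zscan4c at 1.44, germline (0.26, 98.8), trophectoderm (0.50, 99.93), p53 targets (0.56, 100), with Perp at 73.9, Cdkn1a at 48.2 and Btg2, an antiproliferative gene, at 25.6 from 11.7, glycolysis (0.26, 99.99), with Bnip3 at 461, and imprinted genes (0.27, 99.4), among which Peg10 went from 19.7 to 51.7. Within range lay excision repair (-0.07, 53.1), Nodal and primed state (0.09, 87.6), primitive endoderm (-0.03, 23.2), mesoderm (0.52, 92.6), neural ectoderm (-0.12, 6.09), unfolded protein response (-0.12, 33.02), heat shock (-0.20, 10.7), interferon response (-0.16, 6.11), cholesterol synthesis (-0.17, 13.8), histones (-0.06, 2.84), ribosomal proteins (-0.02, 96.7) and fibroblasts (0.29, 91.9). The 10 lowest again held Mmp17 (5.76), Trh (25.9), Nnat, Klhdc7a, Usp26, Tspo2 and Rad23b, with Xpc, the galectin gene Lgals7 (13.0 to 0.861) and Lrrc31 (12.9 to 1.84) added. The 10 highest held Stub1 (747), Chpf2 (31.7) and the unplaced gene model, with Pof1b (0.776 to 68.6), Ncrna00085 (2.06 to 51.3), the histone gene Hist1h2ac (0.215 to 8.19), AU015836 (16.4 to 109), Plekha4 (1.88 to 15.6), Sept1 (23.6 to 132) and Tcte2 (6.46 to 39.5). Lrrc31, Pof1b, Plekha4 and Tcte2 share coordinates with other genes. Of 14821 genes 585 were at least 2-fold higher and 504 lower (275 and 292 protein-coding), and after centring on the median of -0.14, 750 and 370. The authors' deposited table had a p-value under 0.05 for 409 genes, 228 higher and 181 lower. This comparison too rests on 1 library each, without a replicate check.

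Knockdown 2, with an independent hairpin, gave Klf4 at 29.2 RPKM (log2 -1.38), Tfcp2l1 at 60.8 (-1.50), Esrrb at 60.2 (-1.39), Nanog at 209 (-1.26) and Dppa3 at 19.6 (-2.02), with Pou5f1 at 1431 (-0.14) and Sox2 at 133 (-0.44). Pluripotency genes stood at -0.28 (percentile 2.28, or 2.57 with 0.1 as the added constant; 24 of 34 below the median of all genes) and the XPC complex at -1.11 (0.07). Higher than matched lists were 2-cell-like genes (1.54, 100; Zscan4f 4.23), germline genes (0.71, 100; Taf7l 15.7), p53 targets (0.24, 99.95; Cdkn1a 41.6), glycolysis (0.35, 100; Vegfa 60.3; 0.18 with own coordinates) and the Nodal and primed state (0.39, 99.86), where Dnmt3b, a de novo methyltransferase, went from 24.5 to 36.5 though Lefty2 went from 146 to 61.9. Trophectoderm (0.16, 78.3) and the proteasome (-0.34, 2.79) lay inside the range here, with excision repair (-0.19, 12.2), primitive endoderm (0.10, 64.2), mesoderm (0.69, 96.9), neural ectoderm (-0.05, 14.2), unfolded protein response (0.08, 96.9), heat shock (-0.25, 13.1), interferon response (0.23, 73.0), cholesterol synthesis (-0.21, 10.4), histones (0.05, 13.0), ribosomal proteins (-0.11, 94.7), fibroblasts (0.38, 96.6) and imprinted genes (0.07, 78.8). Among the 10 lowest were Tdh (68.9), Plac8 (32.9 to 5.65) and Fos, a subunit of AP-1 (39.9 to 8.28), beside Xpc, Rad23b, Klhdc7a, Usp26, Nnat, Tspo2 and Lrrc31, but Mmp17 stood at 57.5, near its wild-type value. The 10 highest were Stub1 (915), Chpf2 (39.7), Cbx8 (26.1), Vps8 (89.4), Ncrna00085 (26.2), the septin gene Sept1 (175), the pseudogenes Rpl35a-ps3 (75.7), Hmgn2-ps1 (43.0) and Trp53-ps (6.53) and the unplaced gene model. Of 14877 genes 585 were at least 2-fold higher and 535 lower (271 and 296 protein-coding), and after centring on the median of -0.14, 762 and 395. The authors' deposited table had a p-value under 0.05 for 407 genes, 229 higher and 178 lower. There was again no replicate check.

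**Figure D4:**
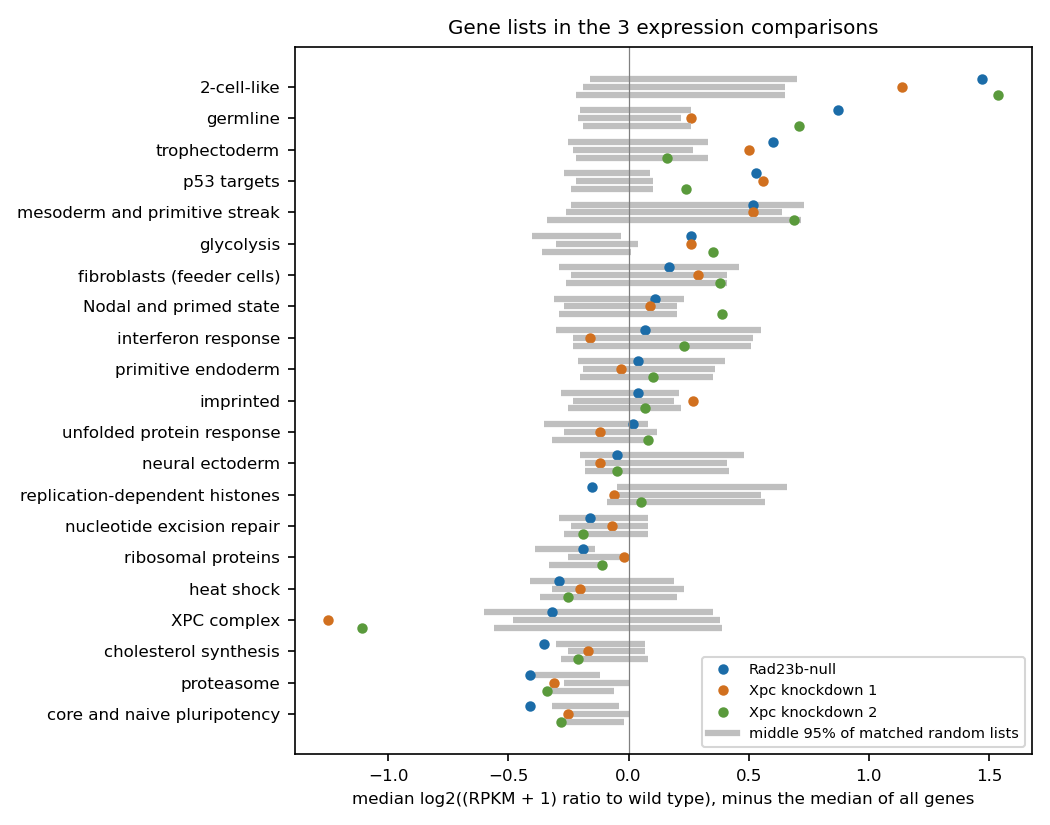
Median log2 ratio of 21 gene lists in each comparison, relative to all genes, with the middle 95% of matched random lists in grey. Pluripotency genes stood at -0.41, -0.25 and -0.28 and 2-cell-like genes at 1.47, 1.14 and 1.54.

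The knockdowns shared much of their difference from wild type. Stub1, which encodes a ubiquitin ligase, Chpf2, Sept1, the paraspeckle RNA Neat1 (7.54 to 42.1 and 39.0) and the Y-linked Eif2s3y (2.26 to 15.1 and 14.7) were among the highest in both, though Stub1 and Chpf2 share listed coordinates with other genes, where a value may be that of the merged locus, and Klhdc7a, Nnat, Usp26, Tspo2, Xpc, Lrrc31, Fos and Rad23b among the lowest. The 10 lowest genes of the 3 comparisons were 15 in all, 5 of them named in each (Klhdc7a, Nnat, Rad23b, Tspo2 and Usp26), and the 10 highest were 18, of which 3 were named in each. Of 15459 genes 313 were at least 2-fold higher in both and 329 lower in both, against 22.1 and 17.4 if independent. Unchanged libraries set against a shared wild-type library gave on average 169 and 169 in simulation (at most 201 and 199), and the covariance of the log2 ratios was 0.370 against 0.214 simulated, an excess of 0.156 (Pearson 0.63 against 0.501). Part of the excess over independence may come from the shared wild-type library. The simulation leaves out differences between the wild-type and Rad23b-null lines, so the excess over the simulation can hold them. Among 12478 protein-coding genes 172 were higher and 191 lower in both (independent 5.97 and 6.93, simulated 9.87 and 10.9), with covariance 0.211 against 0.039. With Rad23b-null cells included, 256 genes were higher and 281 lower in all 3 mutant libraries, and pluripotency was the only list below the matched range in all 3 (though at percentile 4.52 in knockdown 1 with only genes of their own coordinates and 2.57 in knockdown 2 with 0.1 added), beside 4 above it (2-cell-like, germline, p53 targets and glycolysis). The knockdowns are made in the Rad23b-null line, so these libraries also share a cell background, and 20 genes, 19 of them short RNAs, were 2-fold apart in opposite directions.

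Few protein-coding genes differed between the knockdowns and Rad23b-null cells. Xpc itself was among the lowest in both knockdowns relative to Rad23b-null cells, with Cryab, a small heat shock protein gene (21.7 RPKM in Rad23b-null, 3.89 and 2.79 in the knockdowns, 4.00 in wild type), Mitf, Itprip, Ctdsp2, Fmn1, Trps1 and Prmt2, the last of these at 168 against 6.33 and 5.35. The highest were Ncrna00085 (1.93 against 51.3 and 26.2), Lmbr1, Prmt8, Manba, Arhgap27, Grin1 and Stab1. Most of these, such as Prmt2, Trps1 and Cryab, returned to wild-type values, so a change in the single Rad23b-null library alone would look the same. Mitf, Itprip, Fmn1, Lmbr1, Manba, Arhgap27, Grin1 and Stab1 share listed coordinates with other genes, so their values may be those of a merged locus. Between knockdowns and Rad23b-null cells 79 genes were at least 2-fold higher and 159 lower in both (independent 3.71 and 5.33), 186 of them short RNAs. Neither count exceeded the means of 169 and 169 from simulated unchanged libraries with a shared control. The covariance was 0.224 against 0.214 simulated, an excess of 0.010. For protein-coding genes the counts were 11 and 21, beside simulated means of 9.87 and 10.9 (highest 17 and 22). Their covariance was 0.053 against 0.039 simulated (highest 0.051), an excess of 0.014, while differences that share no library (1 knockdown over wild type, the other over Rad23b-null) were not positively correlated (Pearson -0.09 and -0.16). The Rad23b-null library is shared by both differences, so part of the excess over independence may come from it.

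Pluripotency factors held RAD23B regions and were lower without Rad23b, but across the genome genes with and without a region changed by similar amounts. Median log2 ratios with and without a region were -0.154 and -0.181 in Rad23b-null cells (percentile 100 among matched genes), -0.150 and -0.110 in knockdown 1 (38.5) and -0.144 and -0.133 in knockdown 2 (99.9). Among genes that the authors' deposited table calls at least 2-fold lower, 364 of 572 (63.6%), 275 of 432 (63.7%) and 273 of 434 (62.9%) had a region, fewer than the 74.0, 73.2 and 72.8% of genes matched on expression. Among those the authors' deposited table calls at least 2-fold higher it was 494 of 739 (66.9%), 389 of 598 (65.1%) and 412 of 622 (66.2%), against 69.4, 70.1 and 69.3%. Restricted to protein-coding genes the deficit among lower genes was gone (percentiles 45.8, 34.5 and 48.3). RAD23B was mapped in D3 cells and expression in JM8.N4 cells, so regions were not measured in the line whose RNA is compared.

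Genes on chromosome 11 were lower as a whole in every mutant library. Protein-coding genes there stood at -0.38, -0.39 and -0.38 relative to the other chromosomes (1004, 990 and 995 genes), and chromosome 11 genes of all types made up 162 of 694, 117 of 504 and 133 of 535 of the genes at least 2-fold lower (23.3, 23.2 and 24.9%) against 8.47, 8.45 and 8.43% of all genes. Psmb6, Psmb3, Psmc5, Rpl19 (1790 to 965 in Rad23b-null cells), Rpa1 and Aldoc lie there, as do Krt19 and Hand1, which were higher. Eif2s3y, a Y-linked subunit of translation initiation factor 2, went from 2.26 to 13.9 RPKM in Rad23b-null cells, with Uty at 2.22 from 0.309 and Ddx3y at 4.55 from 2.59.

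**Figure D5:**
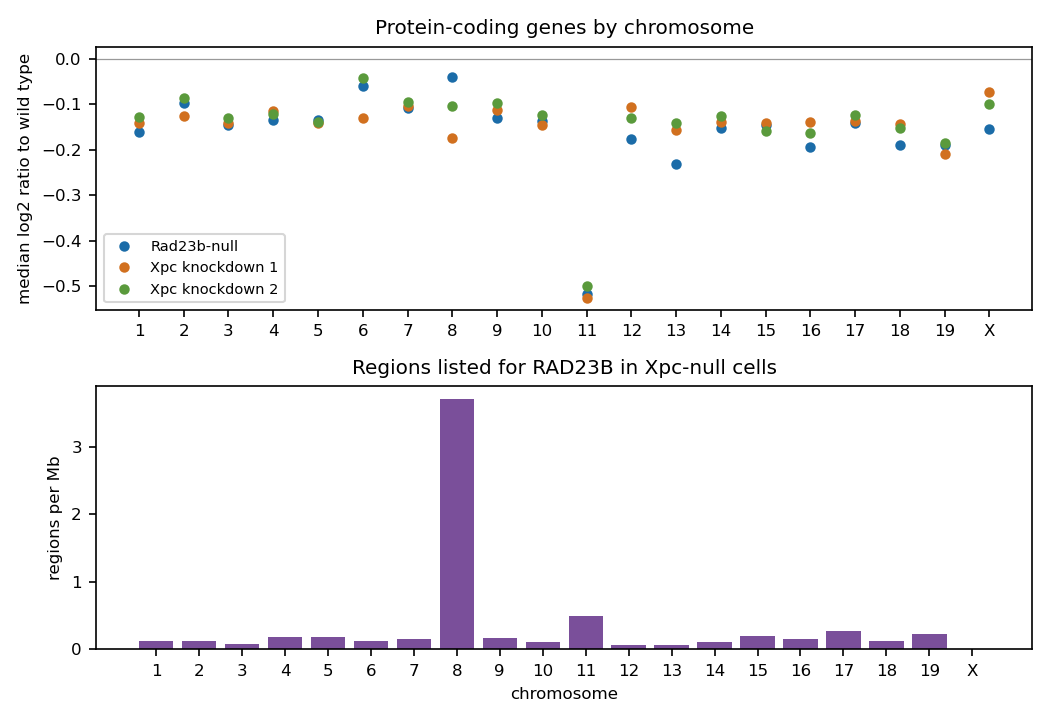
Median log2 ratio of protein-coding genes by chromosome in each mutant library, and Xpc-null regions per Mb by chromosome. Chromosome 11 stood at -0.38, -0.39 and -0.38 relative to the others. Chromosome 8 held 3.71 Xpc-null regions per Mb against 0.0597 to 0.271 on autosomes other than 8, 11 and 15. Chromosomes 11 and 15 held 0.4965 and 0.1996 per Mb.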

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

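In this part the tests of matched chromosome 11 genes, of RAD23B loss on the other chromosomes and of binding kept on chromosome 8 were chosen after the result was seen.

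Xpc-null regions were gathered on chromosome 8, with 477 of 828 (57.6%, 54.2 to 61.0%), or 3.71 per Mb against a median of 0.121 on autosomes other than 8, 11 and 15. Chromosome 11 came next, with 59 regions or 0.4965 per Mb, and chromosome 8 stood far above it. Extra copies of chromosome 8, a frequent gain in stem cell cultures, may account for the gathering there. Each of 6 segments held 9.94 to 42.8 times the 0.136 regions per Mb of other autosomes, as a gain of the whole chromosome could give. Any other cause acting along the whole chromosome would pass this test too, and the segments were uneven (1.35 to 5.83 regions per Mb). RAD23B binding kept there without XPC cannot be told apart, since the wild-type regions overlapped on chromosome 8 stood at the 49.6th percentile of the authors' fold (45.8 to 56.3 on resampling), neither clearly strong nor clearly weak; by IgG-headed reads they stood at 86.5. Wild-type replicate 1 also had dense regions on chromosomes 8, 15 and 11 (35.2, 37.8 and 42.2 per Mb, median of the others 22.1) with more IgG reads per kb (160, 157 and 144 against 127 to 140). In the Xpc-null list IgG-headed reads per kb of region on chromosome 8 (371) lay within the 346 to 384 of the other autosomes. That column belongs to the library in which regions were called, so the calling limit holds it and it cannot tell copy number. RAD23B-headed reads per kb of region were 195 on chromosome 8 and ran from 165 (chromosome 16) to 198 (chromosome 13) on the other autosomes. Copy number was not counted here, and the exchanged or IgG-called columns of the Xpc-null list stay open.

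Chromosome 11 stood lower in all 3 mutant libraries, by -0.38, -0.39 and -0.38 relative to the other chromosomes, where chromosome medians ran from -0.231 to -0.039 in Rad23b-null cells. A difference between libraries that follows expression or locus length is argued against, since set beside matched genes of other chromosomes the chromosome 11 genes still stood at -0.35, -0.35 and -0.35 (resampled -0.38 to -0.32), and so is loss of RAD23B acting alike on all chromosomes, since elsewhere genes with a region stood only -0.05, -0.07 and -0.07 from genes without one. A different number of chromosome 11 copies in the wild-type and Rad23b-null cultures is consistent with all segments lying between -0.29 and -0.44. An effect of RAD23B loss peculiar to chromosome 11 genes with a region cannot be told apart: there genes without a region stood at -0.18, -0.15 and -0.21 and genes with one at -0.35, -0.36 and -0.35 relative to their like elsewhere, but only 46, 42 and 44 genes lacked one. Whether the wild-type culture gained or the Rad23b-null line lost copies, and in what share of cells, stays open.

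Eif2s3y stood at a log2 ratio of 2.19 in Rad23b-null cells, alongside Uty (2.22 RPKM from 0.309) and Ddx3y (4.55 from 2.59), while Gm3395, the last of the 4 Y genes measured, did not rise (0.999 from 1.15); no cause was tested. Of the genes at least 2-fold changed in both knockdowns, 20 went in opposite directions, of which 19 are short RNAs that poly-A libraries measure poorly; the difference between the knockdowns was not tested for these.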

How the results depend on the processing

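In this part the settings that centre each chromosome, leave out chromosome 8 or 11, keep protein-coding genes or genes with their own coordinates, read exact 1 as 1, take regions of fold 2 or more, turn the Xpc-null fold, use 1 kb around the start, use all genes, match on expression and length, or match with genes of RPKM 0 in 1 bin were chosen after the result was seen.

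No called result took the opposite call under another setting, but some directions turned. Higher genes outnumbered lower ones in the report, but not among protein-coding genes, with 5 added, with an RPKM of at least 5 (lower genes 581, 414 and 435) or, in Rad23b-null cells, with exact 1 kept (667 higher, 673 lower). In Rad23b-null cells genes with a region had the higher median in the report (-0.154 against -0.181) and the lower among protein-coding genes (-0.161 against -0.091) and within 1 kb of the start (-0.171 against -0.134). Numbers below run in the order Rad23b-null, knockdown 1, knockdown 2. Of 504 list settings in the 63 expression results 482 stayed the same, 5 weaker and 17 stronger; of 189 in the 21 region results 155, 4 and 30; of 1560 for 390 named-gene results 1438, 83 and 39. No paired analysis was possible because the RNA labels give no pairing, and the numbers in the ChIP titles join each RAD23B library only to the IgG library it is already set against. The authors' q-value alternative at 0.01 was not run, because the tables have no q column. Unless the construction of a setting shows it, the cause was not tested.

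Genes at least 2-fold higher (713, 585 and 585 in the report) depended on the added constant, which weighs on low genes: 1211, 993 and 1035 with 0.1 and 305, 236 and 258 with 5, where lower genes (694, 504 and 535) became 364, 250 and 279. With an RPKM of at least 5, higher genes were 448, 359 and 385. Centring all genes left 462 lower in Rad23b-null cells, and centring each chromosome 429. Protein-coding genes alone gave 362, 275 and 271 higher and 418, 292 and 296 lower, and genes with their own coordinates 389, 337 and 310 higher and 381, 270 and 283 lower; both restrictions drop genes by construction.

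The list calls in the expression comparisons changed as follows. Pluripotency in knockdown 1 moved from percentile 1.37 to 4.52 with own coordinates, and in knockdown 2 from 2.28 to 2.57 with 0.1 added. The proteasome moved in Rad23b-null cells from 1.46 to 3.04 without chromosome 11 and 11.2 with own coordinates, and in knockdown 2 from 2.79 to 0.74 without a filter, 2.13 with each chromosome centred and 2.49 with exact 1 kept. Cholesterol synthesis moved in Rad23b-null cells from 0.865 to 3.79 with own coordinates and in knockdown 1 from 13.8 to 2.27 with each chromosome centred. Neural ectoderm moved without chromosome 11 from 15.7 to 0.10 in Rad23b-null cells and from 6.09 to 0.18 in knockdown 1, and with own coordinates to 0.09, 0.51 and 0.76 (from 14.2 in knockdown 2). The unfolded protein response moved without chromosome 11 from 33.02 to 98.87 in knockdown 1 (median -0.12 to 0.16) and from 96.9 to 99.96 in knockdown 2. Histones in knockdown 1 moved from 2.84 to 1.28 without a filter, 1.49 for protein-coding genes and 2.49 with exact 1 kept. Ribosomal proteins in knockdown 1 moved from 96.7 to 98.4 for protein-coding genes, and fibroblasts from 74.8 to 97.6 in Rad23b-null cells with own coordinates and from 96.6 to 97.8 in knockdown 2 with 0.1 added. Glycolysis stayed above the range with own coordinates, at 0.09 in Rad23b-null cells and 0.18 in knockdown 2 in place of 0.26 and 0.35. Without a filter called lists kept their call but several medians moved by more than 1.5 times. The 2-cell-like list stood at 1.06, 0.47 and 0.61 in place of 1.47, 1.14 and 1.54, glycolysis at 0.10, 0.10 and 0.21 (0.26, 0.26 and 0.35), germline at 0.56, 0.12 and 0.46 (0.87, 0.26 and 0.71), trophectoderm in Rad23b-null cells at 0.33 (0.60), imprinted genes in knockdown 1 at 0.07 (0.27), and in knockdown 2 p53 targets at 0.10 (0.24) and the Nodal and primed state at 0.12 (0.39), while pluripotency stood lower in the knockdowns, at -0.39 and -0.43 (-0.25 and -0.28). Among other settings, 0.1 added gave 2-cell-like medians of 3.12, 2.53 and 3.13 and a histone median of -0.38 in Rad23b-null cells (-0.15; -0.08 with each chromosome centred). Own coordinates gave the XPC complex -2.17 and -1.94 in the knockdowns (-1.25 and -1.11) and germline 0.40 in knockdown 1.

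Genes higher in both knockdowns (313) numbered 729 with 0.1 added, 115 with 5, 172 among protein-coding genes and 189 among genes with their own coordinates. Genes lower in both (329) numbered 169 with 5 added, 219 with each chromosome centred, 191 and 182. Relative to Rad23b-null cells, genes higher in both (79) were 128, 51, 11 and 28 under the 0.1, 5, protein-coding and own-coordinate settings, and genes lower in both (159) were 21 and 59 under the last of these.

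Regions of fold 2 or more numbered 24930, 23856 and 84 in replicate 1, replicate 2 and Xpc-null, where the Xpc-null fold runs against its headings and by them would leave 0. Overlap of replicate 1 with replicate 2 (64.95%) was 58.4% for regions above the median of their list and 69.3% with equal numbers of top regions, and overlap of replicate 2 with replicate 1 (95.91%) 84.5 and 72.7%. Shared wild-type regions overlapped by Xpc-null ones (1.23%) were 0.401% for regions above the median of their list (0.31% with the Xpc-null fold turned), 0.483% with equal numbers, 0.659% without chromosome 8 and 0.868 to 1.13% without a replicate. Xpc-null regions overlapping shared ones (59.8%) were 16.9% for regions above the median of their list (13.3% with the fold turned), 0.483% with equal numbers, 68.1% without chromosome 8 and 59.3 to 64.5% without a replicate.

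Genes with a region (42.6%) were 33.2% within 1 kb of either end, 20.8% for regions above the median of their list, 31.4% within 1 kb of the start, 57.5% with all genes and 43.3 to 48.8% without a replicate. Lists outside the region range (3 of 21) were 6 for regions above the median of their list, 13 when matched on locus length alone, 6 when matched on expression and length, 6 with all genes, 4 with genes of RPKM 0 in 1 bin (glycolysis joined at 97.8) and 5 to 6 without a replicate. Length matching leaves expression uncontrolled, which by construction lets active lists stand out.

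The percentile of the median change of genes with a region (100, 38.5 and 99.9) was 69.5 for protein-coding genes in Rad23b-null cells. In knockdown 1 it was 99.98 without an RPKM filter, 1.06 within 1 kb of either end, 0.85 within 1 kb of the start and 0.33 for protein-coding genes, and in knockdown 2 92.4, 88.4 and 6.36 for these last 3, with 75.9 when matched on expression and length. This result therefore rests on which genes are included. The percentile of the share with a region among higher genes (4.87, 0.325 and 3.26) was, in Rad23b-null cells, 2.17 to 5.86 without a replicate, 0 within 1 kb of either end, 0 within 1 kb of the start, 0.05 for protein-coding genes and 0.18 with all genes; in knockdown 1, 3.58 for protein-coding genes; in knockdown 2, 0.75 to 4.45 without a replicate, 0.045 within 1 kb of either end, 0 within 1 kb of the start, 0.795 for protein-coding genes, 2.14 without chromosome 11 and 0.12 with all genes. Matched on expression and length it was 58.5, 67.7 and 73.5, so no deficit among higher genes was left. Among lower genes (0, 0 and 0) it was 7.39, 5.07 and 10.3 when matched on expression and length, and 45.8, 34.5 and 48.3 for protein-coding genes, so the deficit of regions in these genes was smaller once gene type or locus length was held.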

Other observations

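All 3 tests on pluripotency genes in this part were chosen after the result was seen.

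Pluripotency genes stood at -0.41, -0.25 and -0.28 relative to all genes, with Klf4, Tfcp2l1, Prdm14 and Esrrb far lower and Zfp42 not. Only 1 of the 34 measured members lies on chromosome 11, so a dose effect on genes located there could move the list little. With that chromosome left out or each chromosome centred, the list stayed at percentile 0.9 or lower in all 3 comparisons. This argues only against a dose effect on the members themselves. Whether a different number of chromosome 11 copies changed genes on other chromosomes was not tested. A smaller share of undifferentiated cells cannot be told apart. It would lower all members, and 8, 12 and 10 of 34 stood at or above the median of all genes. Only 6, 8 and 7 stood at or above a ratio of 0, some of them (Klf5, 48.8 to 84.1 RPKM in Rad23b-null cells) also active in trophectoderm. The trophectoderm list stood above the matched range in Rad23b-null cells (0.60; Krt19 15.2 to 78.7) and knockdown 1 (0.50). In knockdown 2 that list lay inside the range (0.16). Loss of activation at genes that hold a RAD23B region cannot be told apart: the 23 members with a region stood at -0.41, -0.27 and -0.36, but only Dppa4 and Nr0b1 lacked one (-0.22, -0.01 and -0.16). A second pair of wild-type and Rad23b-null lines, and RAD23B regions in the line whose RNA was measured, would be needed to separate a RAD23B effect from a difference between cultures.

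Members of the unfolded protein response list went both ways. Ddit3, Chac1 and Trib3, targets of ATF4, went from 9.58 to 29.7, from 15.3 to 40.4 and from 22.3 to 57.8 RPKM in Rad23b-null cells, and the endoplasmic reticulum chaperones Hspa5 (358 to 169), Hyou1 (69.1 to 34.6) and Hsp90b1 (831 to 490) were lower. The division did not follow these functions throughout: Asns, another ATF4 target, went from 439 to 334, 355 and 378 in the 3 mutant libraries, and the chaperone Pdia4 from 91.8 to 83.2, 121 and 232. Of 17 members 9, 8 and 9 stood above the median of all genes. The genes named here were picked after the values were seen, and nothing was tested.

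Mitochondrially encoded protein genes (10) stood at a median log2 ratio of -0.80, -0.35 and -0.43 (up to 0.59 and 0.42 for single genes in the knockdowns), 18 mitochondrial tRNAs at -0.43, 0.08 and -0.17 with a wide spread, and the 2 mitochondrial ribosomal RNAs at 0.47, 0.55 and 0.86. How poly-A selection captured these RNAs was not measured.

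Among regions shared by the wild-type replicates, those of highest fold were not at the pluripotency genes. The region at chr1:53806615-53807308 near Stk17b (426 RAD23B and 39 IgG reads) and the region at chr3:3666704-3667208 (183 and 16) exceeded every region at Pou5f1, Nanog and Esrrb by fold. Of the 10 highest shared regions 0 overlapped an Xpc-null region. Only 17 of the 3883 shared regions in the strongest decile did (0.438%), so 10 regions are too few to show a difference.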
